A study of Mus musculus with 6 samples.

How the data were processed

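Tumors grown from MOC-2, a mouse oral squamous carcinoma line, were taken from male mice after an injection of drug or vehicle into the tumor, per the labels' protocols. Live cells were sorted with a viability dye, each tumor was marked with a multiplexing oligonucleotide tag, and the tumors were pooled in equal ratio for droplet 3' RNA sequencing. The labels list 3 vehicle and 3 treated tumors.

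The authors deposited 1 matrix of whole UMI counts for all tumors together, with 32285 genes, 12 multiplexing tags and 14818 cells. Cell Ranger 7.1 and Seurat 4.1.0 are named per the submitters' processing notes and the series text, with mouse build mm10, while the matrix was written by Cell Ranger 7.0.0 per the file headers. Depth normalization between tumors and filters on cells before deposit are not stated in the labels. Cell barcodes in the deposited file end in a suffix from 1 to 6, and cells that share a suffix are called a barcode set here. No label ties a suffix or a tag to a tumor, so the barcode sets belong to no group.

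For that reason no comparison of treated with vehicle tumors was made: the tests of genes, of gene lists and of cell shares between these groups, fixed before the data were examined, were not run. In their place, as also fixed beforehand, the matrix was described as 1 pooled sample. Values per barcode set are given as single values or as a range and median, with no test. No p-value was computed from cells.

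Cells with at least 500 genes and under 15% mitochondrial counts were kept, which left 13768 cells. Doublets were scored per barcode set with scrublet in scanpy 1.11.5 at an expected rate of 6%. It marked 30 cells, 0.218% of those kept, well under that rate. Doublets may therefore remain, and whether it missed any was not tested. These 30 cells were left out, and leaving out all cells with a score of at least 0.25, which 267 cells reached, was added as an alternative. The remaining 13738 cells were scaled to 10000 counts and log-transformed. From 3000 variable genes, leaving out the genes of the fixed functional lists, 40 principal components were taken (scipy 1.17.1). A graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1 into 23 clusters.

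Marker genes of 16 cell classes were fixed before the data were examined, and the cut-offs of the naming rule were chosen after. Genes seen in at least 10% of a cluster's cells were ranked by their fold over all other cells, with 5 CPM added. A cluster was named when its leading 10 genes held at least 2 markers of a class, more than of any other, and at least 3 of that class's markers reached 2-fold. Clusters with a median doublet score of at least 0.2 were set apart. Clusters that met no name were called unnamed Y-low when 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to under 10 CPM. That class was defined after seeing the data. Another pair of unnamed clusters is called by leading genes, the Ctsk-Acp5 cluster and the Ighm-Ccr7 cluster. The latter was recognised by Ccr7 and H2-Ab1 among its leading genes, and H2-Ab1 is a member of the MHC class II list. No cluster was named for dendritic cells, B or plasma cells, skeletal muscle, skin keratinocytes, adipocytes, Schwann or neural cells, or erythroid cells or platelets.

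Counts were summed per class and scaled to the total of the class, in the usual unit CPM. Clusters with high doublet scores were not ranked. The 20 functional lists were fixed before the data were examined. Some members are also naming markers, such as Gzma and Prf1 for NK cells and Col1a1 and Postn for fibroblasts. Chil3 and Mrc1 are such members for macrophages. The rank of a class on a list that shares its markers is not independent of its name. A list's level is the summed CPM of its members. Its fold is the median, over members with at least 50 counts, of the CPM in a class over that in the sum of all other cells, with a floor of 3 counts. The genes named were chosen by a rule fixed beforehand. In the class with the highest level and in the class with the largest fold of each list, it takes up to 3 members with the highest CPM among those with a fold of at least 2 and at least 50 counts. It adds every target of the listed agents with at least 50 counts. Genes named outside this rule were chosen after their values were seen, and are said to be so.

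Intervals are exact 95% binomial intervals for shares of cells and exact 95% Poisson intervals for CPM. Both cover counting error only, not the spread between tumors. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, leaving out shallower cells. Total gene counts per barcode set ran from 7354560 to 38798439. Gene positions are from GENCODE release M21 on mm10, matched by gene ID.

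The level and fold steps were tested on simulated counts in which genes were changed by a known fold in 1 class. Over 50 genes at each fold, the median ratio of the estimated to the true fold was 0.992 at 0.25-fold and 1.00 at 4-fold. The thinning step gave shares that differed from the exact value by 0.015 percentage points on average over 499 genes, of which 476 lay within 2 standard errors.

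Alternatives fixed beforehand were list genes kept among the variable genes, doublets kept, Leiden resolution 2, at least 200 genes with under 25% mitochondrial counts, at least 1000 genes with under 10%, thinning to 1000 UMIs, and a tag that must hold 90% of a cell's tag counts. Leaving out Xist, Tsix and the Y-linked genes from clustering, the doublet score limit and leaving out each barcode set were added after seeing the data. So were the comparison of each highest class with the intervals of the other classes and with single clusters, the highest class within each barcode set, over classes with at least 20 of its cells, and the levels of targets in their highest class under the alternatives.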

Results

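The series profiled single cells of MOC-2 tumors, a mouse model of head and neck squamous carcinoma, after drug or vehicle was injected into the tumor. The 3 vehicle and 3 treated tumors were tagged and pooled, and the cells could not be assigned to labelled tumors here. The pool is therefore described as 1 sample without replicates, and no difference between treated and vehicle tumors is reported. The matrix held 141434361 gene UMIs, with a median of 7654 UMIs per cell.

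Each barcode set carried 1 main tag. The own tag of the set was the largest tag in 14814 cells and another tag was in 4, and it held at least 90% of the tag counts in 10596 cells. The sets ranged from 901 cells with 7354560 UMIs to 4077 cells with 38798439 UMIs. The 6 sets had 3040, 2370, 901, 4077, 2914 and 1516 cells, in the order of their suffixes, with 31707816, 23041353, 7354560, 38798439, 27572776 and 12959417 gene UMIs. Their main tags and sizes are given without a group, since the labels tie none of them to a tumor.

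Most cells lay in clusters rich in Xist, the noncoding RNA that coats the inactive X chromosome, and poor in Y-linked transcripts, although the labels give male mice. Xist (chromosome X, 103460366 to 103483254, mm10) stood at 1089 CPM in the unnamed Y-low class, with a 95% interval of 1083 to 1095. It stood at 1422 CPM in the MOC-2 tumor-like class, named by its epithelial marker genes. Summed counts of the Y-linked genes were 1.04 CPM in the first, which is defined by a low sum, and 2.19 CPM in the MOC-2 tumor-like class. In the endothelial-like class Xist was at 30.6 CPM (15.8 to 53.5) and the Y-linked sum at 237 CPM. The fibroblast-like class held both in its summed counts, with 353 CPM of Xist and 126 CPM of Y-linked counts. Thinned to 2000 UMIs, 19.6% of its cells had a Xist UMI, 22.96% a Y-linked UMI and 2.87% both. The sums therefore do not show that most of its cells held both, and whether the class mixes cells of different kinds was not tested. Xist and the Y-linked genes were chosen after their values were seen.

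**Figure D1:**
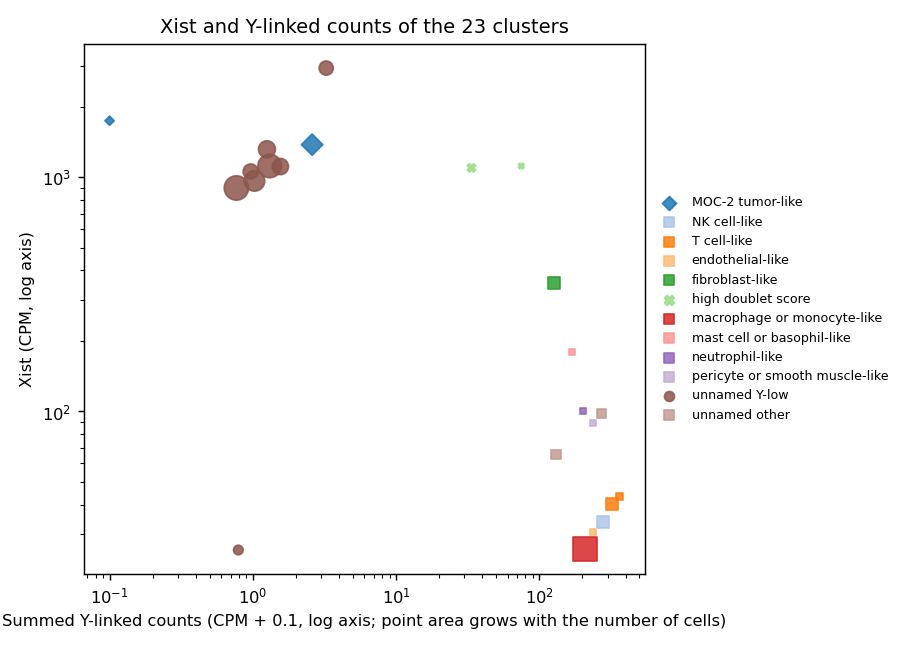
Xist against the summed counts of 4 Y-linked genes, both in CPM on log axes, for each of the 23 clusters, where point area grows with the number of cells. Clusters called unnamed other in the legend are the Ctsk-Acp5 and Ighm-Ccr7 clusters. Y-low clusters lie at the left, 1 of them with little Xist, and the immune and stromal clusters at the right, with the macrophage or monocyte-like cluster at 25.9 CPM of Xist and 207 CPM of Y-linked counts.

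Unnamed Y-low cells made up 64.0% of the 13738 analysed cells (63.2 to 64.8%). Macrophage or monocyte-like cells followed with 14.05% (13.5 to 14.6%), MOC-2 tumor-like cells with 5.78% (5.40 to 6.18%), T cell-like cells with 3.73% (3.42 to 4.06%) and fibroblast-like cells with 3.52% (3.22 to 3.85%). NK cell-like cells made up 2.58% (2.32 to 2.86%), the Ighm-Ccr7 cluster 1.57% and the Ctsk-Acp5 cluster 1.55%. Mast cell or basophil-like, pericyte or smooth muscle-like, endothelial-like and neutrophil-like cells each stayed under 1%, at 0.553, 0.473, 0.451 and 0.386%. Clusters with high doublet scores held 1.32%. The MOC-2 tumor-like name rests on epithelial markers, so its share need not count all tumor cells. Together with the unnamed Y-low cells, also rich in Xist and poor in Y-linked counts, it made up 69.8% (69.0 to 70.6%). That joint share was lowest in barcode set 3, at 53.5%, and highest in set 1, at 76.6%. The neutrophil-like share was 2.80%, from 409 cells in place of 53, with a wider cell filter that moved both limits, to at least 200 genes and under 25% mitochondrial counts. At Leiden resolution 2 the macrophage or monocyte-like and MOC-2 tumor-like shares stood at 8.96% and 2.36%. Without barcode set 6 the neutrophil-like share was 0.234%, and without barcode set 2 the mast cell or basophil-like share was 0.356%.

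**Figure D2:**
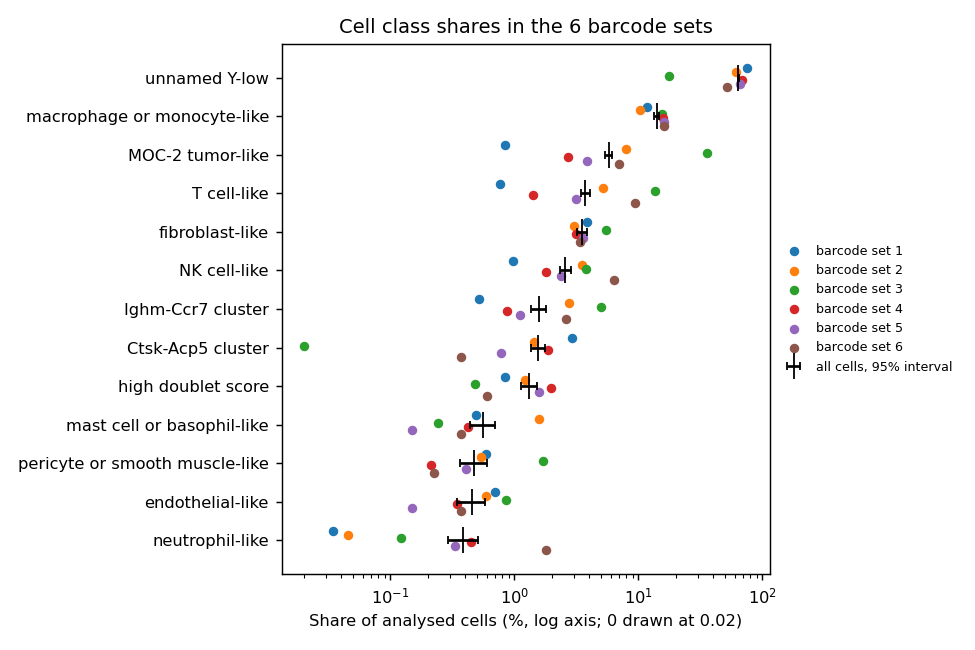
Share of analysed cells in each class, in percent on a log axis, for each barcode set (points) and for all cells with the exact 95% binomial interval (black marks), where a share of 0 is drawn at the left edge. MOC-2 tumor-like shares run from 0.833% to 35.8% over the 6 barcode sets, and unnamed Y-low shares from 17.7% to 75.8%.

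NK cell-like cells had the highest level of the T and NK cell activation and cytotoxicity list, 16284 CPM (16063 to 16507), with 15 of 16 members at 2-fold or more and a median member fold of 119. Gzma and Gzmc, granule proteases of killer lymphocytes, stood at 4501 and 4066 CPM there, and Gzmb at 2522 CPM. Gzma and Prf1 are also NK cell markers of the naming rule, so this rank is not independent of the class name. Of the interferon genes, Ifng was at 264 CPM (236 to 294) in this class, with a fold of 112. Only 2 of the 8 list members had 50 counts in the matrix, and Ifnb1, the other, named after its values were seen, had 0 counts in NK cell-like cells. The interval there, up to 2.89 CPM, covers the 1.91 CPM of unnamed Y-low cells, so no difference in Ifnb1 is shown. With at least 1000 genes per cell and under 10% mitochondrial counts no cluster was named NK cell-like. The cytotoxicity list was then highest in the unnamed cells outside the Y-low class, and the interferon genes in T cell-like cells. In T cell-like cells the checkpoint list had a median member fold of 6.92, with Ctla4 at 576 CPM, Pdcd1 at 105 CPM and Cd274 at 101 CPM. The MHC class I list was also highest in T cell-like cells, at 12264 CPM, with H2-K1 at 3915 CPM and H2-D1 at 1327 CPM. They were the highest class in barcode sets 1 to 5, and in set 6 NK cell-like cells stood at 13322 CPM against 12588 CPM. At Leiden resolution 2 a dendritic cell-like class was highest on this list. H2-K1 and Psme1 were at 2621 and 534 CPM in the Ighm-Ccr7 cluster, where this list had its largest fold of 3.17. Among classes, the proliferation list was highest in T cell-like cells at 4125 CPM, with Hmgb2 at 1763 CPM. The 8 unnamed Y-low clusters differed, and 1 of them, with 949 cells, stood higher at 5262 CPM. Its median member fold was largest in unnamed Y-low cells, at 1.81, with the mitotic genes Ube2c and Cdk1 at 180 and 104 CPM.

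The MHC class II presentation list had its highest level in the Ighm-Ccr7 cluster, at 23215 CPM. All 8 members were at 2-fold or more, with a median fold of 98.5. The member H2-Ab1 is also a leading gene by which this cluster was called, so the rank is not independent of that label. Macrophage or monocyte-like cells followed at 7847 CPM, also with 8 members at 2-fold or more and a median fold of 27.9, and held 36023 counts of the list against 17473 in the Ighm-Ccr7 cluster. The invariant chain gene Cd74 stood at 6639 CPM and H2-Aa at 6480 CPM. The costimulation list was highest in the same cluster at 671 CPM, with a median fold of 45.5, Cd86 at 222 CPM (190 to 258) and Cd80 at 137 CPM (112 to 166). With list genes kept among the variable genes both lists were highest in a dendritic cell-like class. At Leiden resolution 2 the MHC class II list was highest in a B or plasma cell-like class and the costimulation list in a dendritic cell-like class.

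Macrophage or monocyte-like cells held the largest fold of the alternative macrophage activation list, with a median of 28.7 and 12 of 15 members at 2-fold or more. Arg1, which degrades arginine, was at 1270.1 CPM, Pf4 at 1172 CPM and Chil3 at 394 CPM. Chil3 and Mrc1, members of this list, are also macrophage markers of the naming rule. The summed level of this list was nonetheless highest in unnamed Y-low cells, at 6797 CPM, of which the secreted phosphoprotein Spp1 gave 6494 CPM. Within single barcode sets, Y-low cells were the highest class only in sets 4 and 5. Macrophage or monocyte-like cells were higher in sets 2, 3 and 6, at 9766, 7840 and 5801 CPM against 4727, 2000 and 4985 CPM, and NK cell-like cells in set 1, at 9035 CPM against 8751 CPM. Over all sets, Spp1 gave 4105 of the 4639 counts of this list in NK cell-like cells. Chemokines had their largest fold in macrophages as well, at 3.36, with Cxcl2 at 12152 CPM, Ccl4 at 2362 CPM and Cxcl3 at 1149 CPM. The metallothionein and metal handling list was highest there at 3994 CPM, with a median fold of 1.85. Hmox1, the heme-degrading enzyme, made up 2117 CPM of it, and the copper importer Slc31a1 was at 71.0 CPM. The metallothionein genes Mt1 and Mt2, named after their values were seen, were instead highest in fibroblast-like cells, at 1301 and 973 CPM against 489 and 177 CPM in macrophages. Fibroblast-like cells were higher on this list in sets 2 and 5, at 2990 and 4712 CPM against 2781 and 4240 CPM. For hypoxia and glycolysis the largest fold was also in macrophages, at 1.42, while the pooled level was highest in MOC-2 tumor-like cells at 3086 CPM, with Ndrg1 at 398 CPM. Within barcode sets, MOC-2 tumor-like cells were the highest class in none of the 6. Macrophage or monocyte-like cells led sets 1, 2 and 4 (3387, 3270 and 2264 CPM), fibroblast-like cells sets 3 and 5 (4074 and 3079 CPM) and neutrophil-like cells set 6 (3851 CPM). MOC-2 tumor-like cells stood at 2999, 2612, 3735, 2176, 2566 and 3167 CPM. Neutrophil-like cells stood at 3004 CPM (2701 to 3332) on this list, an interval that overlaps, and were the highest class without barcode set 1, 3 or 5. An unnamed Y-low cluster was higher than any class, at 4322 CPM. At Leiden resolution 2 the alternative activation, metal handling and hypoxia lists were each highest in the unnamed cells outside the Y-low class, taken as 1 group. Fewer cells were named macrophage or monocyte-like at that resolution, so a change of name alone is not ruled out.

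Neutrophil-like cells had the highest level of 8 of the 20 lists, from only 53 cells and 119162 UMIs, and 24 of these cells came from barcode set 6. Only there did the class reach the 20 cells asked for in a set, and all 8 lists were highest in it. Sets 1 to 5 cannot show whether this rank holds in them. The type I interferon response list stood at 14115 CPM, with 30 of 32 members at 2-fold or more and a median fold of 6.95. Rsad2 and Isg15, both interferon-induced, were at 2635 CPM (2352 to 2943) and 2073 CPM (1822 to 2348). With doublets kept they were at 1269 and 1150 CPM. The drop was not particular to keeping doublets, since leaving out cells with a doublet score of at least 0.25 gave 1549 and 1353 CPM. Inflammatory cytokine and NF-kB genes reached 19293 CPM, with a median fold of 5.58, and Il1b was at 7972 CPM. Il1b was at 4087 CPM with doublets kept and at 4890 CPM under the doublet score limit. Chemokines reached 63686 CPM, with Cxcl2 at 32930 CPM and Ccl4 at 17212 CPM, but their median member fold was 0.815, with 9 of 21 members at 2-fold or more. Over the alternative settings Cxcl2 ran from 17993 to 59560 CPM in this class. Each of these 3 lists kept neutrophil-like cells as the highest class in 6 of 7 alternative settings.

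The other 5 of these lists mostly lost that rank. NRF2 and oxidative stress (median fold 1.59, with Slc7a11 at 2316 CPM) and the interferon-gamma response (2786 CPM, with Gbp2 at 596 CPM) each kept it in 1 of 7 settings. Checkpoints (1410 CPM, with Cd274 at 629 CPM) and p53 and cell death (median fold 1.96, with Cdkn1a at 990.2 CPM) each kept it in 2. The unfolded protein and integrated stress response (median fold 1.98, with Ppp1r15a at 680 CPM) kept it in 3, and in 3 of the 6 settings that leave out a barcode set. Its interval overlapped that of the Ighm-Ccr7 cluster at 3097 CPM, and cluster 8, an unnamed Y-low cluster, stood above both at 3588 CPM. That cluster had few UMIs (a median of 3699 per cell), a mitochondrial share of 6.67% and 3.63 times the Malat1 of other unnamed Y-low clusters, so RNA quality is not ruled out for its level. The interval of checkpoints overlapped T cell-like cells at 1191 CPM, a class of clusters far apart on this list. Cluster 16 stood at 2470 CPM, above neutrophil-like cells, and cluster 10 at 959 CPM. In sets 1 to 5 T cell-like cells were the highest class on it, from 1060.2 to 1333 CPM. The interferon-gamma response had its largest median fold in endothelial-like cells, at 2.57, with Cxcl9 at 268 CPM. Of 126 levels of named genes recomputed in neutrophil-like cells under the alternatives, 62 were over 1.5 times lower and 8 over 1.5 times higher. No cluster was named neutrophil-like with at least 1000 genes and under 10% mitochondrial counts.

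TGF-beta target genes were highest in fibroblast-like cells, at 20664 CPM, with a median fold of 3.04 and 8 of 13 members at 2-fold or more. The matrix genes Col1a1 and Postn stood at 13763 and 2216 CPM. Both are also fibroblast markers of the naming rule, so this rank is not independent of the class name. Among classes, the heat shock list was highest in MOC-2 tumor-like cells at 11559 CPM, with Hspb1 at 3724 CPM and a median fold of 1.02. The largest median fold was 1.11, in unnamed Y-low cells, with 0 members at 2-fold. Cluster 8, with the same few UMIs, mitochondrial share and Malat1 level, stood higher than any class, at 17503 CPM. MOC-2 tumor-like cells were the highest class in 4 of 6 sets. The Ctsk-Acp5 cluster was higher in set 4, at 10141 CPM against 8570 CPM, and NK cell-like cells in set 6, at 18059 CPM against 11564 CPM.

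**Figure D3:**
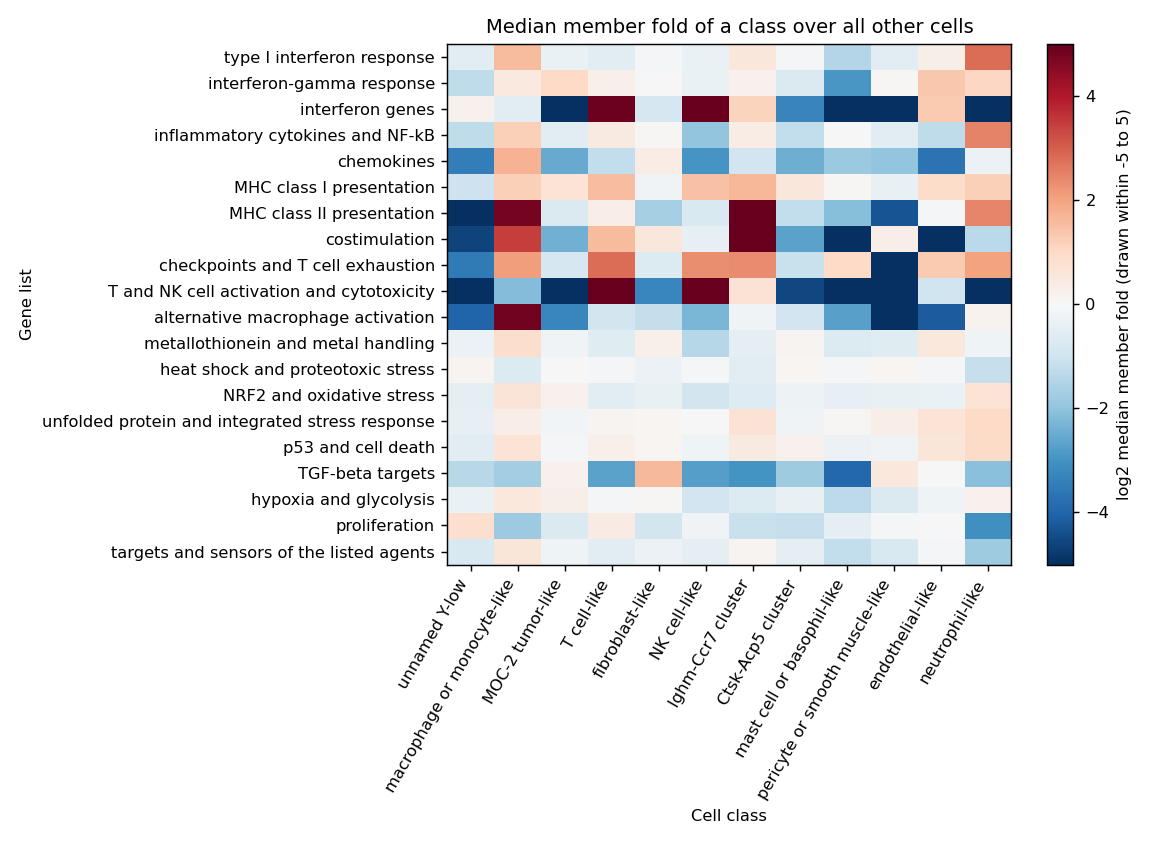
Median member fold of each functional list in each class over all other cells, as log2 on a color scale that stops at both ends, where red is above and blue below the other cells. MHC class II genes stand at 98.5-fold in the Ighm-Ccr7 cluster, and cytotoxicity genes at 119-fold in NK cell-like cells.

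The protocols list agents aimed at several immune targets without saying which were given to the treated tumors, and the levels of these targets show which cells carried them. Arg1 (chromosome 10, 24915221 to 24927484, mm10) was highest in macrophage or monocyte-like cells at 1270.1 CPM (1238 to 1303), against 16.6 CPM in unnamed Y-low cells. At Leiden resolution 2, where fewer cells were named macrophage or monocyte-like, it was highest in the unnamed cells outside the Y-low class. Thinned to 2000 UMIs, 41.9% of 960 macrophage or monocyte-like cells had an Arg1 UMI, with 970 shallower cells left out, and 42.0% did before thinning. The share was 0.830% in NK cell-like cells, taken as a background, and the median depths were 1995 and 2788 UMIs. Other ranked classes ran from 0% in pericyte or smooth muscle-like cells to 29.4% in neutrophil-like cells (10.3 to 56.0%). MOC-2 tumor-like and unnamed Y-low cells had 6.41% and 3.22%. Tnfrsf9, which encodes the receptor 4-1BB (chromosome 4, 150914562 to 150946102), was at 635 CPM (593 to 679) in T cell-like and 503 CPM (465 to 544) in NK cell-like cells. The lead of T cell-like cells rests on cluster 16 at 1539 CPM, since cluster 10, the larger of the pair, stood at 471 CPM. After thinning, 51.0% of NK cell-like and 50.0% of T cell-like cells had a Tnfrsf9 UMI, with 113 and 283 cells left out. Before thinning, 50.9% of T cell-like cells had one. In unnamed Y-low cells the thinned share was 2.96%, and the median depths of T cell-like and unnamed Y-low cells were 1820 and 11270.5 UMIs.

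Arg2 and Nos2, the inducible nitric oxide synthase, were highest in neutrophil-like cells at 378 CPM (275 to 505) and 109 CPM (58.1 to 187). Over the alternative settings that name this class, Arg2 ran from 178 to 531 CPM and Nos2 from 55.6 to 117 CPM in it. Nos2 stood at 84.1 CPM (75.9 to 92.9) in macrophage or monocyte-like cells, and the intervals of the 2 classes overlap. Ido1 and Ido2, which degrade tryptophan, were low in every class and highest in MOC-2 tumor-like cells, at 17.3 and 3.12 CPM, and Ido2 was at 1.17 CPM at Leiden resolution 2. The adenosine receptor gene Adora3 was at 139 CPM (96.4 to 194) in mast cell or basophil-like cells. Tlr7, an RNA sensor, was at 36.8 CPM in macrophage or monocyte-like cells. The sensor genes Tmem173 (STING) and Ddx58 (RIG-I) were highest in endothelial-like cells at 133 CPM and neutrophil-like cells at 151 CPM, and Mavs, the adaptor of RIG-I, in the Ctsk-Acp5 cluster at 14.8 CPM. Tgfb1 was highest in NK cell-like cells at 197 CPM, and Tgfb2 and Tgfb3 in pericyte or smooth muscle-like cells at 324 and 54.9 CPM. The receptors Tgfbr1 and Tgfbr2 were highest in the Ctsk-Acp5 cluster at 246 CPM and in fibroblast-like cells at 283 CPM. Nos3 was highest in endothelial-like cells at 99.5 CPM, as was Vcp at 395 CPM, while Nploc4 was highest in macrophage or monocyte-like cells at 39.6 CPM. Of the 19 targets with at least 50 counts, 13 kept their highest class in all 7 alternative settings, and Nos2 did in 2. For 10 of the 19, Nploc4 and Mavs among them, the interval of at least 1 other class overlapped that of the highest. Single unnamed Y-low clusters stood above the highest class for Tgfb3 (57.5 CPM, in cluster 8), Tgfbr2 (301 CPM) and Nploc4 (40.1 CPM). For 8 of the 19 the highest class had at least 20 cells in all 6 barcode sets, and 3 of them, Arg1, Ido2 and Tnfrsf9, were highest in it in each set. Ido1 and Tgfb1 were in 4 of 6 sets, Tgfbr2 in 3 of 6, Tlr7 in 5 of 6, Nploc4 in 2 of 6, Tgfbr1 in 4 of 4 and Mavs in 2 of 4. The other 9 could be ranked in 1 set at most, which leaves their rank untested across sets. Ido2 had only 27 counts in MOC-2 tumor-like cells over all sets, so its rank in each set rests on very few counts. The intervals of 7 other classes overlapped that of its highest class. The whole list of targets was highest in macrophage or monocyte-like cells, at 2255 CPM, with a median fold of 1.54. At Leiden resolution 2 this list was highest in the unnamed cells outside the Y-low class.

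**Figure D4:**
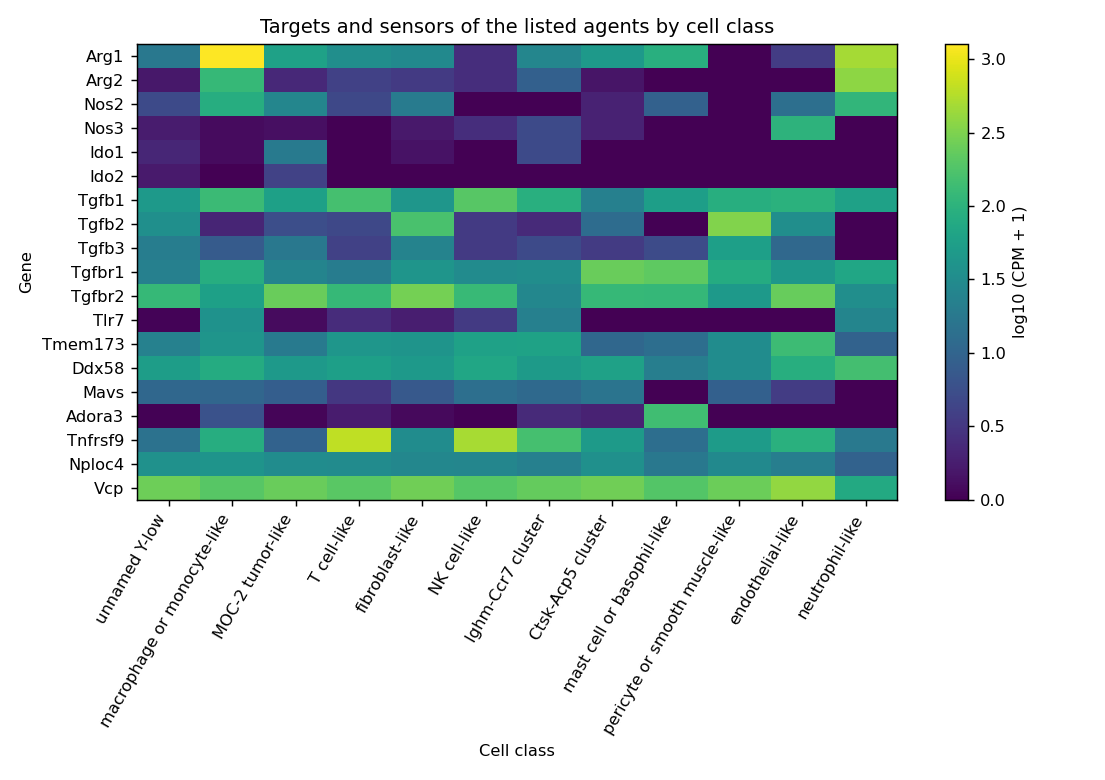
Levels of the 19 targets with at least 50 counts in each class, as log10 of CPM + 1. Arg1 reaches 1270.1 CPM in macrophage or monocyte-like cells and Tnfrsf9 635 CPM in T cell-like cells.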

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

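Counts of 3 multiplexing tags that were the main tag of no barcode set lay above the 3 counts that a count of 0 allows. Tag 303 had 5 counts, tag 308 had 4 and tag 309 had 108, of which 97 were in barcode set 1. All tags together had 84624924 counts. No outlier test was run over the barcode sets, since the labels put them in no group, and no biological explanation was tested.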

How the results depend on the processing

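No paired analysis was possible because no cell maps to a labelled tumor. For the same reason the alternatives for comparisons between groups (DESeq2, other size factors, no count filter, replicate block, left-out replicates, estimated set correlation, exact permutation within replicate numbers) were not run. Leaving out barcode sets, the doublet score limit and clustering without Xist, Tsix and Y-linked genes were chosen after seeing the data.

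Unnamed Y-low cells made up 67.4% at Leiden resolution 2, 60.9% with the wider cell filter (at least 200 genes, under 25% mitochondrial counts), 72.3% with the narrower one (at least 1000 genes, under 10%) and 64.9% under the doublet score limit. Macrophage or monocyte-like shares in the first 3 of these settings were 8.96, 15.4 and 8.32%. MOC-2 tumor-like cells were at 2.36% at resolution 2 and 5.22% without Xist and Y-linked genes. With the narrower filter, T cell-like cells were at 1.27%, the Ighm-Ccr7 cluster at 1.27% and mast cell or basophil-like cells at 0.329%. With the wider filter, mast cell or basophil-like cells were at 0.773% and neutrophil-like cells at 2.80%. High doublet score clusters were at 0.975% with list genes kept, 0.924% with the wider filter, 0.318% under the score limit and 1.09% without Xist and Y-linked genes. These filters moved both limits together, and the cause was not tested, nor for the other settings. Classes with no cluster of their name in a setting, such as NK cell-like and neutrophil-like with the narrower filter, give no value there.

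Without each barcode set in turn, shares ran from 60.9 to 67.0% for unnamed Y-low, 13.4 to 14.8% for macrophage or monocyte-like, 3.86 to 7.09% for MOC-2 tumor-like, 3.11 to 4.62% for T cell-like and 2.17 to 3.00% for NK cell-like cells. They ran from 1.34 to 1.84% for the Ighm-Ccr7 cluster, 1.19 to 1.74% for the Ctsk-Acp5 cluster, 1.06 to 1.45% for high doublet scores, 0.356 to 0.652% for mast cell or basophil-like, 0.234 to 0.479% for neutrophil-like, 3.40 to 3.68% for fibroblast-like, 0.395 to 0.572% for pericyte or smooth muscle-like and 0.387 to 0.526% for endothelial-like cells.

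Of the 20 lists, 10 kept their highest class at resolution 2 and 10 with the narrower filter, and 14 to 20 did in the other settings. Only 3 kept it in all 7. Of the 19 targets, 14 to 19 kept it. Without a barcode set, 17 to 20 lists and 18 to 19 targets did. Thinned to 1000 UMIs, 34.0% of macrophage or monocyte-like cells had an Arg1 UMI and 36.0% of T cell-like cells had a Tnfrsf9 UMI. CPM of the named genes moved past the counting interval in 172 of 544 values, by ratios from 0.374 to 2.24. Of the 73 beyond 1.5 times, 70 were in neutrophil-like cells.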

Other observations

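Of the tests in this part, those of Y-linked counts in endothelial-like against MOC-2 tumor-like cells and of UMIs per cell in Y-low against T cell-like cells were chosen after their results were seen. Levels of 3 antigen presentation and interferon-induced genes, chosen after their values were seen, are listed for the barcode sets with suffixes 1 to 6 in order. The sets are assigned to no tumor, and no test was run. In unnamed Y-low cells B2m stood at 1043, 1085, 1012, 1959, 2298 and 2053 CPM. H2-K1 stood at 369.8, 468, 432, 881, 1126 and 980.1 CPM and Isg15 at 106, 109, 103, 278, 557 and 382 CPM. Sets were ordered by level and the largest gap was taken. For B2m it parted sets 1 to 3 from sets 4 to 6 in unnamed Y-low, macrophage or monocyte-like and NK cell-like cells. For H2-K1 the gap lay there in unnamed Y-low cells and in no other class compared. For Isg15 it parted set 5 in unnamed Y-low, fibroblast-like and NK cell-like cells. The other classes parted the sets differently. With sets ordered by B2m in MOC-2 tumor-like cells, the largest gap parted set 6, and set 3 lay above sets 4 and 5. Ordered by H2-K1 there, and by either gene in fibroblast-like cells, it parted set 1. For Isg15 in MOC-2 tumor-like cells it parted sets 1 to 4 from sets 5 and 6. In macrophage or monocyte-like cells B2m was at 3049.9, 3220.2, 3560.4, 5384, 5055 and 5799 CPM. In T cell-like cells it ran from 3269 to 4205 CPM, with a median of 3591 CPM. The MHC class II presentation list, fixed beforehand, took another order in macrophage or monocyte-like cells, at 7791, 8890, 15251, 8267, 5768 and 6275 CPM. Macrophage, T, NK, mast cell and neutrophil classes, without the unnamed Ighm-Ccr7 cluster, together made up 13.9, 20.6, 33.1, 19.7, 22.0 and 34.0% of the cells of the sets. The Ctsk-Acp5 cluster, led by osteoclast-type genes, held 0 of 825 cells in barcode set 3 and 2.92% of barcode set 1.

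Xist and Y-linked counts part the clusters. With Xist, Tsix and all Y-linked genes left out of clustering, 99.9% of the cells of Y-low clusters fell in Y-low clusters again, which argues against the clustering genes as the cause. Cells of Y-low clusters had 6.08 times the median UMIs of T cell-like cells (11074.5 against 1820), and their lower quartile of 6871 lay above the upper quartile of 2847 in T cell-like cells. That argues against shallow cells that miss Y-linked counts. The Y-linked level of endothelial-like cells was 108 times that of MOC-2 tumor-like cells, and a candidate explanation is that Y-low cells come from the injected line and Y-positive cells from the male mice. Over 19 autosomes, chromosome-wide shifts of unnamed Y-low over fibroblast-like cells and of MOC-2 tumor-like over macrophage-like cells correlated with r = 0.868 across chromosomes, which are not replicates. This rests on few chromosomes: r was 0.669 without chromosomes 8 and 19 and 0.127 without 11 as well, and Spearman's rho was 0.377. These chromosomes were left out because their unnamed Y-low shifts lay furthest from the median, so the fall of r does not speak against shared shifts. Chromosomes 8, 11 and 19 had the largest shifts in both profiles, at 0.467, 0.378 and 0.403 and at 0.734, 0.540 and 0.508 in log2. Chromosome 5 came next in both, at 0.225 and 0.299. The fibroblast-like class, the reference for the unnamed Y-low shifts, also held Xist.

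Among unnamed Y-low clusters, cluster 12 was poor in Xist and led by ribosomal protein genes, and cluster 8 had high Xist, few UMIs and a high mitochondrial share. Malat1, a nuclear RNA, in cluster 12 was at 0.0173 times its level in the other unnamed Y-low clusters, and at 0.0175 times after thinning, which keeps proportions and so says nothing about depth. In cluster 8 it was at 3.63 times that level. Loss of nuclear RNA in the first and of cytoplasmic RNA in the other may account for these clusters, and neither was tested apart from Malat1.

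Cluster 15 was picked out for its macrophage markers, Xist, high UMI counts and high doublet scores. After thinning, 5.73% of its 157 cells had both a Xist and a Y-linked UMI, against 0.312% of macrophage or monocyte-like cells. The share of 50% set beforehand for doublets was out of reach at this depth, since only 8.28% of its cells had a Y-linked UMI, so that test decides nothing. For macrophages that took up RNA, the limits set beforehand were Xist under 0.5 times the level of unnamed Y-low cells and no more UMIs than macrophages. Xist stood at 1.01 times that level. The median of 10038 UMIs was 0.891 times that of unnamed Y-low cells and lay far above the 1995 of macrophage or monocyte-like cells. Since the cluster was picked out with high UMI counts in view, it could not meet these limits, and they decide nothing. The limit set beforehand against uptake, at least the UMIs of unnamed Y-low cells, was not met either. Pairs of cells in 1 droplet and uptake of RNA both stay open, and uptake of larger amounts of RNA was not tested.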
